A study of Mus musculus with 15 samples.

How the data were processed

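Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, so that the number of reads in a region reflects how accessible it was. Per the labels, each library came from tumour cells of 1 pancreatic tumour cell clone. The clones were grown under the skin of C57BL/6 mice, and 50000 tumour cells were sorted from each tumour 3 weeks after implantation. The labels class each clone by the T cell content of its tumours. They list 15 samples. The table used here had columns for 13 of them, 6 T cell high and 7 T cell low clones, and every column of per-sample values was matched to a sample by the clone name in its title. The 2 T cell intermediate clones were not analysed here, so the planned comparisons with them, their parental pairs and the models over all 15 samples were not run. Replicate numbers follow accession order and pair nothing. Each library was a different clone in a different tumour, and p-values of single peaks and of single values per library measure the spread between clones. The position of a clone is an exception, since its peaks were chosen with the group labels of the other clones. The camera p of a gene list also compares genes with genes and depends on the correlation assumed between them. Clones of 1 parental tumour counted as separate units, except where parental tumour or a sum of clones is named.

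The deposited values were whole-number counts of reads per merged peak, not normalized. Per the file headers they were made with featureCounts 1.5.3 on a list of merged peaks, with no option for read pairs or strand, from alignments whose names say that duplicates had been removed. The genome build was mm10 and DESeq2 was also named, per the submitters' processing notes. The aligner, the peak caller, the rule for merging peaks and any shift of reads for the transposase offset are not given in the sources used here. Counting reads rather than pairs means that both ends of a DNA fragment can be counted in the same peak, so counts are not independent molecules, and counting intervals would cover counting error only. The peaks were defined over merged samples, and a region open in 1 clone alone can therefore be listed. The table held 67945 peaks with lengths from 151 to 3711 bp (median 708 bp), of which 1560 were on chromosome X, 4 on chromosome Y and 0 on the mitochondrial chromosome.

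Peaks were matched to 21883 protein-coding genes of a gene table of assembly GRCm38.p6, the assembly that mm10 represents. The table gives gene start and end without strand, exons or transcripts. The planned definition of a promoter by transcription start was therefore replaced by the gene end, meaning either end of the gene record. A gene-end peak lay within 1 kb of a gene end (12894 peaks), and a linked peak had its nearest gene end within 50 kb (50104 peaks). Where a gene had several gene-end peaks, the 1 with the highest mean count was used. Whether a peak lay in an exon, intron or untranslated region was not analysed here. Motif accessibility and a check of GC content needed a genome sequence and were not run.

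Counts were analysed in R 4.3.3 with edgeR 4.0.16. Peaks were filtered with filterByExpr by group, which left 59252 peaks, and libraries were scaled by TMM. T cell high was compared with T cell low by the quasi-likelihood F-test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are T cell high over T cell low. Levels are CPM (counts relative to the TMM-scaled library size), and log2 CPM used a prior count of 2. Total counts in peaks ran from 968296 to 7369228 per library. On data simulated from these libraries, with 57799 peaks tested, the test called 14.3% of peaks changed 2-fold, 71.1% of those changed 4-fold and 99.5% of those changed 8-fold. It called 16 of 57214 unchanged peaks, and with no change simulated 4.564% of peaks had an unadjusted p under 0.05. In this simulation, with counts drawn independently and changed peaks among those tested, 8-fold changes were found and most 2-fold ones missed. In the real comparison a peak at Pcdh7, 7.69-fold lower in T cell high, had an adjusted p of 0.125 by the F-test. Changes near 8-fold can therefore also have been missed there.

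Gene lists were tested with camera in limma 3.58.1 on 1 gene-end peak per gene (12208 genes) with a preset correlation of 0.01, adjusted over 25 lists, with an estimated correlation and fry beside it. The lists held 564 genes, of which 345 had a tested gene-end peak. They covered myeloid-recruiting factors, T cell and dendritic cell chemokines, MHC class I antigen presentation, interferon response, immune checkpoints and co-stimulation, epithelial identity, mesenchymal identity, endoderm and classical pancreatic cancer genes, basal and squamous genes, RAS-MAPK feedback and AP-1, TGF-beta and BMP pathway, WNT pathway, prostaglandin and EphA2 axis, glycolysis and hypoxia, cell cycle and housekeeping. The other 9 were markers of other cells that a tumour or its site can hold, namely T and NK cells, pan-leukocyte, macrophages and monocytes, neutrophils, B cells, fibroblasts and pericytes, endothelial cells, skin and muscle of the implantation site, and acinar and islet cells. Gapdh and Pgk1 stand in both the glycolysis and the housekeeping list. A list's score in a library was its mean log2 CPM minus the mean over all gene-end peaks.

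The groups, main tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text names, from each list, up to 4 members that passed the test or, where none passed, the member with the smallest p. It always names every linked peak of Cxcl1 and the gene-end peaks of Cd274, Epcam, Cdh1, Zeb1, Gata6, Myc, Ptgs2 and Epha2. The rule also asked for the 10 peaks with the smallest adjusted p below 0.05 in each direction, of which there were 0. The peaks with the smallest p that are named instead were chosen after their values were seen.

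Single values per library were compared by an exact permutation test (two-sided) in scipy 1.17.1 under Python 3.11.15, with Benjamini-Hochberg adjustment within each family. The position of a clone on the axis from T cell low to T cell high was its mean log2 CPM over peaks higher in T cell high minus that over peaks lower, relative to the midpoint of the group means, with the peaks chosen in a fit without that clone. Peaks passing the threshold existed in 1 of the 13 such fits, so the 500 peaks with the smallest p in each direction, the choice named beforehand as the other option, were used for every clone. The pair of clones from parental tumour 6499 was treated in the same way. That clones share a parental tumour was read from the number before the letter c in their names. Correlations across libraries used 100000 resamples. Runs of at least 20 neighbouring peaks with a rolling median, over 9 peaks, beyond 1.5 in size on the log2 ratio to the median of the other libraries were listed as blocks. In the block at Cdkn2a the longest run of neighbouring peaks with at most 2 counts was then sought in every clone, a rule chosen after seeing the data.

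The alternatives were scaling by DESeq2 size factors, total counts or loess offsets, DESeq2 1.42.0, limma-voom without and with parental tumour as a random effect, no filter, a mean count of at least 20, stricter thresholds, autosomes only, the sum of clones 6419c1 and 6419c5, offsets from 5 Mb windows for regional DNA dosage, gene-end windows of 2 kb, all linked peaks, and leaving out each library in turn. Sums of linked peaks per gene, libraries thinned to the smallest total, parental tumour as a fixed factor and the position test without each library were chosen after seeing the data. For the splits of the samples, 100 of the 1716 splits into groups of 6 and 7 were used, the real split included. No library was a copy of another, since the chi-square per peak between pairs of libraries ran from 3.194 to 14.16.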

Results

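Chromatin accessibility was profiled by ATAC-seq in tumour cells sorted from implanted mouse pancreatic tumours. Each of the 13 libraries came from a different tumour cell clone, 6 from clones whose tumours are labelled T cell high and 7 from clones whose tumours are labelled T cell low. The T cell high clones, in replicate order, were 2838c3, 6421c2, 6499c4, 6555c3, 6620c1 and 7160c2. The T cell low clones were 2699c4, 6419c1, 6419c5, 6422c1, 6499c3, 6556c3 and 6694c2. Reads were counted in 67945 merged peaks of the mm10 genome. Total counts in peaks were 3198000 ± 1695000 (SD, n = 6) in T cell high and 3020000 ± 2103000 (SD, n = 7) in T cell low libraries, and ranged from 968296 in 7160c2 to 7369228 in 6419c1. The main comparison asks where chromatin in the tumour cells themselves differs between tumours with many and with few T cells.

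Of the 10 peaks with the smallest p between the groups, 7 lay at Skint6, Pdzrn3, Tek and Sema5a, where the T cell high clones were on average more accessible, and at Pcdh7, where they were less accessible. The other 3, on chromosomes 9 (17557356 to 17558385), 3 (53991114 to 53991850) and 1 (168967112 to 168967978), lay outside gene records and over 50 kb from a gene end. They had log2 fold changes of 2.64, 2.82 and 1.58. Inside the gene record of Skint6, a butyrophilin-like gene of the Skint family, a peak on chromosome 4 (113262629 to 113263262) had 17.6 ± 9.88 CPM (SD, n = 6) in T cell high and 2.48 ± 1.29 CPM (SD, n = 7) in T cell low clones, a log2 fold change of 2.78 (SE 0.45). All 6 T cell high clones lay above all 7 T cell low clones at this peak. Next to Pcdh7, which encodes a protocadherin, a peak on chromosome 5 (57714879 to 57715449, 696 bp from a gene end) had 2.14 ± 1.23 CPM (SD, n = 6) against 14.9 ± 9.16 CPM (SD, n = 7), a log2 fold change of -2.94 (SE 0.49). The 9 tested peaks at Pcdh7 had a median of -1.79, and of -0.15 with offsets for regional dosage. These offsets are window medians that include the Pcdh7 peaks, and only 2 tested peaks lay outside the gene within 2 Mb. The fall therefore cannot tell regional dosage from a change at the gene. Peaks inside Pdzrn3, a ubiquitin ligase gene (chromosome 6, 101271526 to 101272520), Tek, the angiopoietin receptor gene (chromosome 4, 94745782 to 94747003), and Sema5a, a semaphorin gene (chromosome 15, 32401821 to 32402841), had log2 fold changes of 2.64, 1.85 and 1.81.

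None of these peaks passed the edgeR quasi-likelihood test, in which 0 of 59252 peaks had an adjusted p under 0.05 and the smallest adjusted p was 0.125. At an unadjusted p under 0.05 the test gave 4046 peaks (6.83%), 2290 higher and 1756 lower in T cell high. limma-voom also called 0 peaks, with 5046 at an unadjusted p under 0.05, and DESeq2 called 46 peaks, 35 higher and 11 lower, with 5689 at an unadjusted p under 0.05. The DESeq2 calls included the peaks above at Skint6 (adjusted p = 4.27e-05), Pcdh7 (4.27e-05), Tek (0.00209), Pdzrn3 (0.00254) and Sema5a (0.00641). Leaving out 1 library changed the edgeR result: without 2838c3 (T cell high replicate 1) edgeR called 42 peaks, 38 higher and 4 lower, of which 20 were among the DESeq2 calls, and leaving out any other library gave 0. Without 2838c3 10.7% of peaks had an unadjusted p under 0.05. With parental tumour as a fixed factor edgeR called 91 peaks, 71 higher and 20 lower, of which 2 were among the DESeq2 calls. That fit rests on 6499c4 against 6499c3, the only parent with a clone in each group, with 1 residual degree of freedom, and of the peaks named here it called Cldn3. When the counts of all peaks linked to a gene were summed, 1 of 14726 genes passed, Skint6, whose summed counts rose in T cell high (log2 fold change 2.49, SE 0.36, adjusted p = 0.0132).

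Of the 25 gene lists, epithelial identity was the only one called, by camera with a preset correlation alone (adjusted p = 0.000995, and adjusted p = 0.923 with an estimated correlation). Of 32 listed genes 28 were measured at a gene-end peak, and 19 of these had a fold change above and 9 below zero, with a mean log2 fold change of 0.32 and a median of 0.12. The members with the smallest p were Cldn3 and Epcam. Cldn3, which encodes a claudin of tight junctions (chromosome 5, 134985631 to 134986567), had 38.2 ± 30.1 CPM (SD, n = 6) in T cell high and 6.18 ± 4.40 CPM (SD, n = 7) in T cell low clones, a log2 fold change of 2.65 (SE 0.56). Epcam, an epithelial adhesion molecule (chromosome 17, 87636119 to 87637408), had 50.03 ± 30.3 CPM (SD, n = 6) against 19.9 ± 8.69 CPM (SD, n = 7), a log2 fold change of 1.34 (SE 0.39) that was 0.88 with offsets for regional dosage. The membrane protease gene St14, the epithelial splicing regulator Esrp1 and the claudin gene Cldn7 had log2 fold changes of 1.52, 1.56 and 1.15, and Rab25, a small GTPase of epithelial membrane traffic, had -1.24. Cdh1, the gene for E-cadherin, had -0.08 (0.06 with dosage offsets, and from -0.17 to -5.01e-05 when 1 library was left out), and the keratin genes Krt8, Krt18 and Krt19 had 0.10, 0.19 and -0.41. These 6 genes from Cldn3 to Rab25 are the members with an unadjusted p under 0.05 and were named after their values were seen, apart from Cldn3 and Epcam.

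By camera the epithelial list had p = 3.98e-05 with the preset and p = 0.0928 with the estimated correlation. By fry in limma the adjusted p was 0.931 for a common direction and 0.756 for change in either direction. No member passed over all peaks, and 2 passed when adjusted over the list alone, Cldn3 (adjusted p = 0.00263) and Epcam (adjusted p = 0.0332). The score of the list was -0.58 ± 0.46 (SD, n = 6) in T cell high and -0.92 ± 0.17 (SD, n = 7) in T cell low clones, a difference of 0.34 that was within the spread between clones (exact permutation test, two-sided, p = 0.0944, adjusted p = 0.619). The clone 2838c3 had the lowest score of all, -1.42, and the other T cell high clones lay above every T cell low clone, the closest at -0.63 against -0.64. Without 2838c3 the mean log2 fold change was 0.44 and Cldn3 passed over all peaks (edgeR adjusted p = 0.0155). Without 7160c2 (T cell high replicate 6) the mean was 0.22 and the list no longer passed (adjusted p = 0.0856).

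**Figure D1:**
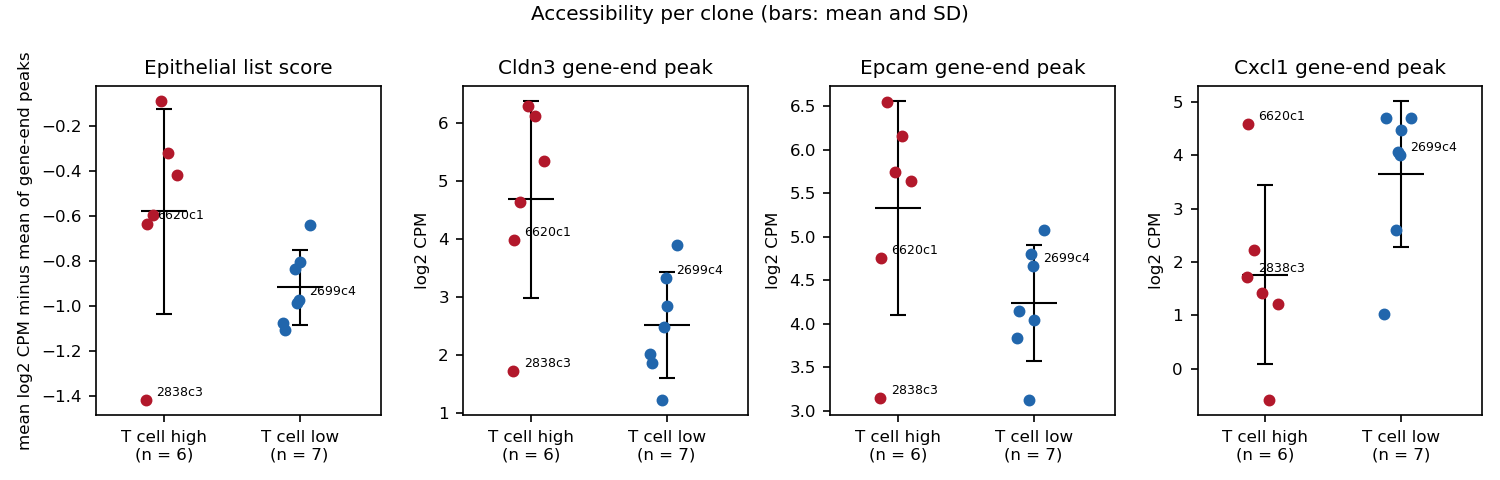
Accessibility in each clone, with points for clones and bars for the mean and SD of the 6 T cell high and 7 T cell low clones. The first panel gives the score of the epithelial list (mean log2 CPM minus the mean of gene-end peaks) and the others log2 CPM of the gene-end peaks of Cldn3, Epcam and Cxcl1; the T cell high clone 2838c3 lies lowest in the first panel, at -1.42, and 6620c1 lies apart from the other T cell high clones at Cxcl1.

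Lists on immune recruitment and recognition were examined because the groups are defined by T cell content. Of the genes for antigen presentation by MHC class I, 13 of 21 measured members were higher in T cell high, with a mean log2 fold change of 0.13 (camera, adjusted p = 0.131). Psmb9 and Tap1 share a peak, so these members stand for 20 peaks, 12 of them higher, with a mean of 0.14. The peak of Tapbpl is also that of Cd27 in the T and NK cell list. The member with the smallest p was H2-M3, a non-classical class I gene, at 0.66. The score of this list was 0.00455 ± 0.12 (SD, n = 6) in T cell high and -0.18 ± 0.10 (SD, n = 7) in T cell low clones (exact permutation test, two-sided, p = 0.00816, adjusted p = 0.204 over 25 lists). Without 6421c2 (T cell high replicate 2) the mean log2 fold change of the list was 0.04, and without 6620c1 (T cell high replicate 5) the list passed with the preset correlation (mean 0.17, adjusted p = 0.049), and not with an estimated correlation (adjusted p = 0.921). Myeloid-recruiting factors went the other way, with 11 of 15 members lower in T cell high, a mean of -0.28 (adjusted p = 0.438) and -0.14 without 6419c1 (T cell low replicate 2). In each of these lists 0 members passed the edgeR test over all peaks or adjusted over the list alone, 0 were called by DESeq2, and 1 member had an unadjusted p under 0.05.

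Cxcl1, a chemokine that attracts neutrophils, had the smallest p in that list. Its gene-end peak (chromosome 5, 90890833 to 90891740) had 5.61 ± 8.78 CPM (SD, n = 6) in T cell high and 15.7 ± 9.40 CPM (SD, n = 7) in T cell low clones, a log2 fold change of -1.48 (SE 0.69, adjusted p = 0.723). Among the T cell high clones 6620c1 alone was at 23.3 CPM and the others lay between 0 and 4.04 CPM. Among the T cell low clones 6422c1 was at 1.36 and 6499c3 at 5.36 CPM, and the others lay between 15.3 and 25.3 CPM. The log2 fold change ranged from -2.86 to -1.23 when 1 library was left out. The value of -2.86 came from dropping 6620c1, the clone that opposes it. The other 5 peaks linked to Cxcl1, on chromosome 5 from 90875851 to 90885683, had log2 fold changes of 0.15, 0.45, -0.39, -0.10 and 0.39. When 1 library was left out these ranged from 0.04 to 0.25, 0.33 to 0.55, -0.73 to -0.24, -0.26 to 0.10 and 0.03 to 0.61. No peak of Cxcl1 passed the test.

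The remaining immune lists did not pass either. T cell and dendritic cell chemokines (8 measured) had a mean of 0.14 and a median of -0.08 (adjusted p = 0.771). Cx3cl1, a membrane-bound chemokine, was at 0.66 and at 0.20 without 6421c2. The interferon response (24 measured) had a mean of 0.01 (adjusted p = 0.771), with Socs1, a brake on cytokine signalling, at -0.46. Immune checkpoints and co-stimulation (13 measured) had a mean of -0.08 (adjusted p = 0.84), with Tnfrsf14 at -0.81, or -0.36 without 6556c3 (T cell low replicate 6), and Cd274, which encodes PD-L1, at 0.12, or 0.02 to 0.20 when 1 library was left out (31.3 ± 3.42 CPM, SD, n = 6, against 28.5 ± 8.20 CPM, SD, n = 7). The peak of Cd274 also overlaps the gene record of Plgrkt, so it cannot be assigned to Cd274 alone. The prostaglandin and EphA2 axis (11 measured) had a mean of -0.05 (adjusted p = 0.84). In that list Ptgs2, the gene for cyclooxygenase-2, had -0.37 (-0.55 without 6421c2 and -0.19 without 6419c1), the receptor gene Epha2 had 0.09 (0.02 to 0.17 when 1 library was left out) and the ephrin gene Efna1 had -0.53. In these 4 lists 0 members passed the edgeR test over all peaks or adjusted over the list alone, and 0 were called by DESeq2. An unadjusted p under 0.05 was seen for 2 interferon response genes and 1 gene of the prostaglandin list.

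Lists of tumour cell state and signalling were not called. Mesenchymal identity (21 measured) had a mean of -0.12 (adjusted p = 0.771), with N-cadherin gene Cdh2 at -0.78 and the transcription factor gene Zeb1 at -0.28. Endoderm and classical pancreatic cancer genes (23 measured) had a mean of 0.06 (adjusted p = 0.438), with the intestinal factor gene Cdx2 at 0.44, or 0.28 without 6421c2, and Gata6 at -0.22, or -0.40 without 6620c1, -0.08 without 7160c2 and -0.14 without 6499c3. Basal and squamous genes (11 measured) had a mean of -0.16 (adjusted p = 0.879), with Sox2 at -1.74, or -0.90 without 6422c1 (T cell low replicate 4). The TGF-beta and BMP pathway (23 measured) had a mean of -0.18 (adjusted p = 0.84), with the feedback gene Skil at -0.27, and the WNT pathway (17 measured) a mean of 0.03 (adjusted p = 0.784), with Lgr5 at 0.49. Glycolysis and hypoxia (22 measured) had a mean of -0.06 (adjusted p = 0.84), with Hif1a at -0.96, the cell cycle list (25 measured) -0.06 (adjusted p = 0.84), with the cyclin gene Ccnb1 at -0.36, and housekeeping genes (20 measured) -0.06 (adjusted p = 0.84), with Ppia at -0.29. In these lists 0 members passed the edgeR test over all peaks or adjusted over the list alone, 0 were called by DESeq2, and 1 mesenchymal and 1 basal gene had an unadjusted p under 0.05.

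RAS-MAPK feedback and AP-1 genes (27 measured) had a mean of -0.19 and a median of -0.05 (camera, adjusted p = 0.84). In the edgeR test 1 member passed when adjusted over the list alone, Myc (adjusted p = 0.0478), with 0 over all peaks. The gene-end peak of Myc, a growth-promoting transcription factor gene (chromosome 15, 61984233 to 61985892), had 53.9 ± 10.5 CPM (SD, n = 6) in T cell high and 410.3 ± 907.7 CPM (SD, n = 7) in T cell low clones, a log2 fold change of -2.93. That value, which also enters the mean of the list, came from 2699c4 (T cell low replicate 1), at 2468 CPM. The other T cell low clones had 67.4 ± 27.3 CPM (SD, n = 6), and without 2699c4 the log2 fold change was -0.33. DESeq2 was run with its default setting, under which an outlying count in a group of at least 7 libraries can be replaced. It gave -0.30, which is therefore not a second estimate from all counts as they stand. The same setting held for all DESeq2 calls given above.

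Over all 25 lists, camera compares a list with the other genes, whose median log2 fold change was -0.07, and in 8 lists its direction was up while the mean was below zero. These were T and NK cells, glycolysis and hypoxia, the prostaglandin and EphA2 axis, immune checkpoints, cell cycle, housekeeping, macrophages and monocytes, and pan-leukocyte. In 3 lists the mean and median had opposite signs, namely the T cell and dendritic cell chemokines, B cells (mean 0.10, median -0.03) and pan-leukocyte (mean -0.01, median 0.01).

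Markers of other cell types were compared to see whether the sorted cells held different amounts of them. Few of these genes had a gene-end peak that passed the filter: 4 of 28 genes of T and NK cells, 7 of 20 pan-leukocyte genes, 7 of 22 genes of macrophages and monocytes, 2 of 18 neutrophil genes and 4 of 12 B cell genes were measured. For fibroblasts and pericytes it was 3 of 19, for endothelial cells 3 of 18, for skin and muscle of the implantation site 5 of 18 and for acinar and islet cells 3 of 18. Mean log2 CPM of pan-leukocyte genes was 3.54 ± 0.35 (SD, n = 6) in T cell high and 3.59 ± 0.28 (SD, n = 7) in T cell low clones. For T and NK cells it was 3.88 ± 0.30 (SD, n = 6) against 3.78 ± 0.60 (SD, n = 7), although the groups are named for the T cells of their tumours. Among the 4 measured T and NK genes, Cd27 shares its peak with Tapbpl of the MHC class I list. That peak is therefore not particular to T cells.

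The differences in mean log2 CPM for the 9 lists were 0.12 for B cells, 0.09 for T and NK cells, -0.42 for acinar and islet cells, 0.06 for endothelial cells, -0.0042 for fibroblasts and pericytes, -0.02 for macrophages and monocytes, 0.08 for neutrophils, -0.04 for pan-leukocyte and -0.15 for skin and muscle. In exact permutation tests (two-sided) their adjusted p lay between 0.86 and 0.967. At single genes, the T cell factor gene Tcf7 had a log2 fold change of -0.06 (-0.22 to 0.05 when 1 library was left out), the leukocyte tetraspanin gene Cd53 -0.55, the Fc receptor gene Fcgr3 -0.85, Il1r2 0.18 (-0.10 to 0.28), the complement receptor gene Cr2 1.22 (0.55 without 6555c3, T cell high replicate 4), Postn 0.10 (-0.21 to 0.29), the endothelial factor gene Sox17 1.28 (0.76 without 6421c2), the skin gene Ivl -0.81 (-0.52 without 6422c1) and the acinar factor gene Bhlha15 -0.81 (-0.53 without 6421c2). None passed the edgeR test over all peaks or adjusted over the list alone, and 0 members of these lists had an unadjusted p under 0.05 or a DESeq2 call at a gene end. Tek, whose peak away from the gene ends is given above, is a listed endothelial gene without a tested gene-end peak. By camera these 9 lists had adjusted p of 0.771 for acinar and islet cells, 0.84 for endothelial cells, neutrophils, B cells, T and NK cells, fibroblasts and pericytes, and skin and muscle, 0.879 for macrophages and monocytes and 0.962 for pan-leukocyte.

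The next question was whether a clone kept out of the choice of peaks still fell with its own group. On the axis from T cell low to T cell high, 4 of 6 T cell high clones lay above zero and 6 of 7 T cell low clones below it. Of these 4 clones, 7160c2 was hardly apart from zero, at 0.0037, and the T cell high clone 6421c2 lay at -0.51. The position was 0.11 ± 1.13 (SD, n = 6) in T cell high and -0.28 ± 0.29 (SD, n = 7) in T cell low clones, a difference of 0.39 that did not exceed the spread (exact permutation test, two-sided, p = 0.411). The peaks were chosen with the group labels of the other clones, and the choice was not repeated in each permutation. This p is therefore approximate. The T cell high clone 2838c3 lay lowest, at -1.78, below every T cell low clone. Without 2838c3 the difference was 0.77, a value raised by dropping the clone that opposes it, and without 1 of the other libraries it lay between 0.16 and 0.52. At the 42 peaks called without 2838c3, this clone was at -1.97.

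**Figure D2:**
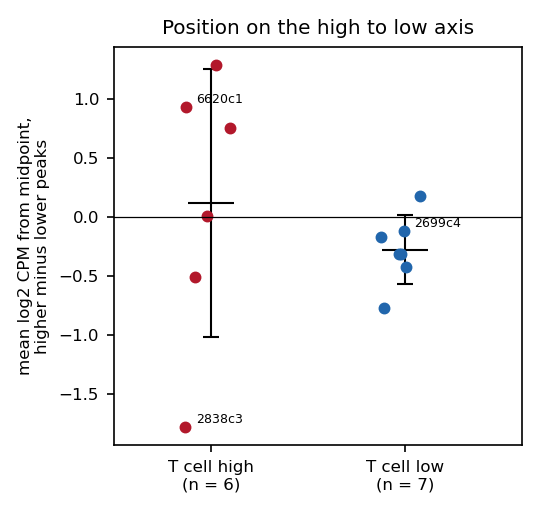
Position of each clone on the axis from T cell low to T cell high, as mean log2 CPM over 500 peaks higher minus 500 peaks lower in T cell high, relative to the midpoint of the groups, with peaks chosen without that clone. Points are clones and bars the mean and SD; 2838c3 lies at -1.78, while 6 of 7 T cell low clones lie below zero.

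Parental tumour 6499 gave a clone to each group, 6499c4 (T cell high) and 6499c3 (T cell low), which allows the groups to be compared within a parent, with 1 library per clone. Of the 500 peaks with the smallest p that were higher in T cell high among clones of other parents, 382 (76.4%) were higher in 6499c4 than in 6499c3, with a median log2 ratio of 0.85. Of the 500 peaks lower in T cell high, 190 (38%) were higher in 6499c4, with a median of -0.22. Over all 55542 peaks tested the share was 50.7%. Over all peaks, 6499c3 was nonetheless closest to 6499c4 (r = 0.77 across peaks, which are not independent replicates). However, 6499c4 was also the closest clone of 6422c1, of another parent (r = 0.803), and was itself closest to 6555c3 (r = 0.848). The value within the parent therefore shows no likeness particular to it.

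Profiles as a whole were compared between clones. The median correlation across peaks was 0.708 between T cell high clones, 0.74 between T cell low clones and 0.709 between clones of different groups. The closest clones were 6499c4 and 6555c3 (r = 0.848) and 6419c1 and 6419c5, of the same parent, reached 0.812. The T cell high clone 2838c3 was closest to the T cell low clone 2699c4 (r = 0.817). Each of the other T cell high clones was closest to a T cell high clone. For 6421c2, 6555c3, 6620c1 and 7160c2 that clone was 6499c4, which was also the closest clone of the T cell low clones 6422c1 and 6499c3. The library of 6499c4 held 5936823 counts in peaks, and that of 6419c1, the closest clone of 6419c5 and 6556c3, held 7369228. Whether sequencing depth sets which clone is closest was not tested, so these matches do not show a likeness among T cell high clones. Of the T cell low clones, 6419c1, 6419c5 and 6556c3 were closest to a T cell low clone and the others to a T cell high clone. The share of counts at gene ends was 40.7% ± 1.68 (SD, n = 6) in T cell high and 42.2% ± 3.198 (SD, n = 7) in T cell low libraries, and the share on chromosome X was 1.59% ± 0.237 (SD, n = 6) and 1.77% ± 0.49 (SD, n = 7). Chromosome Y peaks held 0.00284% ± 0.00168 (SD, n = 6) and 0.00464% ± 0.0026 (SD, n = 7) of counts, and the TMM factor was 0.999 ± 0.0488 (SD, n = 6) and 1.003 ± 0.0546 (SD, n = 7). None of these or the total counts differed by more than the spread between libraries (exact permutation tests, two-sided, adjusted p from 0.807 to 0.878).

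Neighbouring peaks of single clones stood far from most other libraries over 2 regions. In 2699c4 (T cell low replicate 1) all 63 peaks from 61875029 to 62561648 of chromosome 15, which holds Myc, were raised, with a median log2 ratio of 5.11 (34.4-fold), and the flanking peaks had medians of -0.42 and -0.31. In 6694c2 (T cell low replicate 7) 31 peaks from 89257656 to 89515408 of chromosome 4, which holds the cell cycle inhibitor genes Cdkn2a and Cdkn2b, had a median of -4.11. They held 10 counts in total, 1.54% of the median of the other libraries, with flanking medians of 0.05 and 0.13. Inside this region 6556c3 (T cell low replicate 6) also lacked signal over a shorter stretch, with 2 counts in the 5 neighbouring peaks from 89294181 to 89349449, which reach both genes, 1.53% of the median of the other libraries. All other clones but 6694c2 had at least 137 counts there. A partial fall would not show in a search for peaks with at most 2 counts. In 2838c3 (T cell high) log2 ratios were -1.88 to -1.10 at peaks from 89294181 to 89311419. They were -2.81 to -0.88 from 89360343 to 89446675, and -0.39 to 0.36 between these stretches. These regions were chosen after their values were seen.

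**Figure D3:**
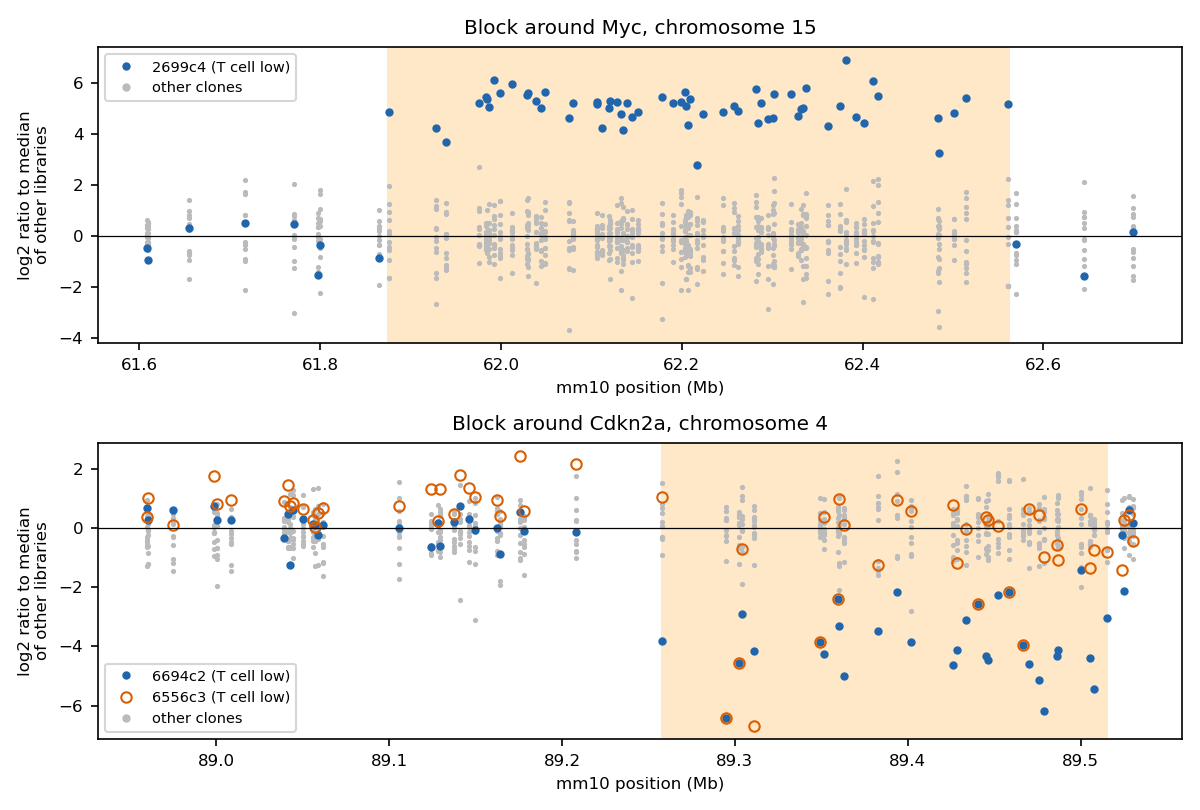
Log2 ratio of each clone to the median of the other libraries at peaks along chromosome 15 around Myc and along chromosome 4 around Cdkn2a (mm10, Mb). Filled coloured points are 2699c4 and 6694c2, open circles in the lower panel 6556c3, grey points the other clones and the shaded spans the blocks; the block in 2699c4 has a median of 5.11 and that in 6694c2 a median of -4.11.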

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

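The tests of the raised block around Myc were chosen only after the result was seen. In 158 groups of values, each holding 6 or 7 clones, 10 had a highest or lowest clone with an unusually wide gap to the next, and chance gives this in about 1 in 20 groups.

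In the T cell low group, 2699c4 stood at a log2 CPM of 11.27 at Myc (next clone 6.91), 6499c3 at 3.55 at H2-M3 (next 4.43), and 6419c5 at 4.28 at the cyclin gene Ccnb1 (next 5.39). In the T cell high group, 6421c2 stood at 3.08 at Cdh2 (next 5.27) and at -0.58 at Bhlha15 (next 2.04), and 2838c3 at 1.33 at Pdzrn3 (next 4.34). The library of 6419c1 had 7369228 counts, with 3283310 in the next of its group. Among list scores, fibroblasts and pericytes were at -1.87 in 6499c3 (next -1.26), macrophages and monocytes at -1.17 in 7160c2 (next -1.65), and skin and muscle of the implantation site at -0.40 in 6422c1 (next -0.83).

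The Myc value belongs to a block of 63 peaks in 2699c4, of which 100% were over 4-fold above the mean of the other libraries. Scaling or depth of the library would have raised the flanking peaks as much, and the median log2 ratio of the block minus that of its flanking peaks was 5.44 (SD of 40 flanking peaks 0.781). Blocks were picked as runs that stand apart on scaled counts, with the flanking peaks outside the run. A gap was thus largely set by that choice, and this difference is no separate test of scaling. A difference between the groups is argued against by the other clones, since without 2699c4 the log2 fold change at Myc was -0.33. With sharp edges on both sides, the block is consistent with a gain of DNA copies in this clone, which more reads from more DNA would produce without any change in how open the chromatin is. No DNA sequencing of the clone was used here, so this stays a hypothesis.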

How the results depend on the processing

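Alternatives with summed or thinned counts, parental tumour as a fixed factor, and the position test without each library, were chosen only after the results were seen. The count of called peaks stayed at 0 in edgeR and limma-voom under every scaling, filter, threshold and offset tried, was 46 with DESeq2 and 1 with counts summed per gene, and 91 in edgeR with parental tumour as a fixed factor (11.05% at an unadjusted p under 0.05), a fit that rests on 6499c4 against 6499c3. Leaving out each library in turn gave 0 to 42 called peaks (42 without 2838c3), 5.06 to 10.7% of peaks at an unadjusted p under 0.05, 0 to 2 called lists (0 without 7160c2, 2 without 6620c1), a mean of 0.22 to 0.44 for the epithelial list and a position difference of 0.16 to 0.77. The number of called lists was 0 with an estimated correlation, where the mean of the epithelial list is 0.32 by construction, and 0 with thinned libraries, where it was 0.134 (adjusted p = 0.385, within a range over its alternatives from 1.95e-07 to 0.923). Thinning removed 9 of its 28 members from the test. With the same peaks kept, 2 lists were called, the second being MHC class I antigen presentation (adjusted p = 0.743 with an estimated correlation).

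Some small values changed sign, and the cause was not tested. Postn had -0.0185 in limma-voom, -0.0245 with parental tumour, and -0.113 when thinned with the same peaks, where Il1r2 had -0.0725 and Epha2 -0.0386. Epha2 had -0.0296 when thinned and Cdh1 0.0567 with dosage offsets. Over all linked peaks the differences were -0.0648 for B cells, 0.00702 for fibroblasts, -0.0883 for neutrophils and 0.0319 for pan-leukocyte. Leaving out libraries gave -0.217 to 0.0498 for Tcf7, -0.105 to 0.279 for Il1r2, -0.209 to 0.286 for Postn, -0.261 to 0.101 for the Cxcl1 peak at 90881667, -368800 to 903800 for total counts, and -0.0183 to 0.00727 for the TMM factor. Of 1258 values of named genes and of the MHC class I and myeloid-recruiting lists under alternatives, 1227 kept direction and side of the threshold, 17 passed only in the alternative and 14 changed sign. With these depths, from 968296 counts, and this spread between clones, 14.3% of simulated 2-fold changes were recovered. Replicate numbers pair no clones. With parental tumour as a random effect 0 peaks were called. Models with the intermediate clones and motif accessibility were not run.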

Other observations

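The tests of other cell types, of thinned libraries with the same peaks, of the groups along the first principal component, of focal dosage, of the block around Cdkn2a and of the same peaks in 6556c3 were chosen only after the result was seen. The first principal component, over 57399 peaks not linked to any listed gene, held 18.2% of the variance and had 2838c3 (T cell high) at its low end, -140.3, and 6555c3 (T cell high) at its high end, 152.5. It was 33.85 ± 95.57 (SD, n = 6) in T cell high and -29 ± 47.14 (SD, n = 7) in T cell low clones (exact permutation test, two-sided, p = 0.154). It rose with the epithelial score (r = 0.795, permutation p = 0.0013, adjusted p = 0.0338 over 26 relations; rho = 0.78, p = 0.00246, adjusted p = 0.064), and r was 0.656 without 2838c3 and 6555c3, the 2 clones farthest from the median. The WNT, endoderm and TGF-beta lists had r = 0.698, 0.691 and -0.659, with adjusted p of 0.0801, 0.0801 and 0.0943, and without these 2 clones r was 0.33, 0.638 and -0.678. Sequencing depth did not set this axis, since its r with log2 total counts was -0.00471.

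The higher epithelial list in T cell high was weighed against technical explanations. Regional DNA dosage is argued against by the mean log2 fold change of 0.34 with dosage offsets. More reads from other cell types in T cell low libraries stay open, since the score of their markers differed by -0.0177 (T cell low minus high, SD of T cell low 0.263), few of these genes had a tested gene-end peak and their lists went both ways. Unequal depth was tested first by thinning with the filter applied again, which left 0.134 and met the forecast for a depth effect, but the 19 members still tested had a mean of 0.126 at full depth and the 9 lost had 0.743, and with the same members kept the thinned mean was 0.325. Chance was not excluded: 13 of 100 splits of the clones, the real one included, gave a p for this list as small as 3.98e-05, the smallest of the others was 2.09e-09, 60 of the other splits called at least 1 of the 25 lists, and a candidate explanation is that clones vary along an epithelial axis on which the T cell high clones other than 2838c3 lie high, and whether that goes with T cell content stays open.

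Chance was not excluded for the peaks at an unadjusted p under 0.05 either. As many as the real 4046 were found in 18 of 100 splits, the real one included, and the highest of the others had 6360. At least 1 peak passed the adjusted threshold in 9 of the other splits, with 44 at most, in a split that set 2838c3 and 5 T cell low clones against the other T cell high clones and 2 T cell low clones.

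Neighbouring peaks moved together at some of the loci named above. At Skint6 the 2 tested peaks had a median log2 fold change of 2.76 and at Pdzrn3 all 9 peaks were higher, with a median of 2.46, while the median of peaks outside the gene within 2 Mb was 0.384 and 0.228, which argues against dosage of that whole region. A focal dosage change stays open, since the nearest peaks outside, 5 on each side, had a median of 0.749 at Pdzrn3 with a highest value of 2.53, and of 0.865 at Skint6, where the closest lay over 1 Mb away on each side. At Pcdh7 all 9 peaks were lower, with a median of -1.79 (-0.15 with dosage offsets), and the surrounding region had -1.53 but only 2 peaks, so that dosage of the region and a change at the gene cannot be told apart. The dosage offsets include the Pcdh7 peaks themselves, so the fall to -0.15 does not decide between the 2. These loci were picked for their small p, and a regulatory difference at Skint6 or Pdzrn3 remains a hypothesis.

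In 6694c2 (T cell low) 96.8% of the 31 peaks in the block around Cdkn2a were over 4-fold below the median of the other libraries. Scaling of the library would move the flanking peaks as much. The median of the block minus that of its flanking peaks was -4.19 (SD of 40 flanking peaks 0.75). The block was picked for standing apart from the peaks beside it, so this difference is no separate test of scaling. A loss of DNA in this clone could give these values and stays a hypothesis. The loss of signal was not in 6694c2 alone, since 6556c3 (T cell low) had 2 counts where the other libraries had a median of 320, over 5 peaks that reach Cdkn2a and Cdkn2b, and a cause was not tested there. In 2838c3 (T cell high) signal was lower over part of the block, with log2 ratios of -1.88 to -1.10 at peaks from 89294181 to 89311419. A cause was not tested for 2838c3 either. In all, 11 blocks of at least 20 peaks were found in 6 clones, and in 2 of them, these at Myc and Cdkn2a, at least 90% of the peaks were beyond 4-fold. The other 9 had medians between -2.22 and 1.82. As at Myc, no DNA sequencing was used here.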
